A study of Mus musculus with 8 samples.

How the data were processed

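RNA was measured in mouse small intestinal organoids, which are cultures of epithelial cells from the intestines of young mice. Per the labels, the cells came from C57BL/6 mice that carry an inducible transgene for the 4 reprogramming factors Pou5f1, Sox2, Klf4 and Myc. Nothing in the labels says that the transgene was switched on in these samples. Organoids were left untreated or given 6 Gy of X-rays and were collected at day 4 or day 7. The labels do not say from when the days were counted. Each of the 4 groups holds 2 libraries, 8 in all, made per the labels' protocols from poly-A selected RNA with a stranded kit.

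The authors deposited a table of expected counts per gene and a table of TPM (counts scaled for gene length and library size) per gene, each with 1 column per library, per the file headers. Expected counts are estimates that share reads between genes where a read fits more than one, so they need not be whole numbers. Per the submitters' processing notes, FastQC, Trim Galore, STAR 2.7.3a and RSEM 1.3.3 were used, and the genome builds GRCm39 and mm10 are both named, without the role of either. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of a gene and of its antisense partner may be mixed. No coordinates are given in either table and none are printed here.

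Both tables hold 55416 Ensembl gene IDs. A symbol was found for 52083 of them by exact match to GENCODE M21, used only for names, and 3333 had none. Gene length was deposited count over TPM. Of the genes, 30447 had at least 1 count, and 30068 of these had a symbol. Expected counts were rounded to whole numbers, which changed 11.45% of the values. The filter of edgeR (filterByExpr, minimum count 10, minimum total 15) left 14063 genes, of which 33 had no symbol, and kept in each library a share of its counts whose lowest value was 99.8%. For 7976 of the tested genes the deposited counts were whole in all 8 libraries, within 0.001.

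The total of expected counts per library ran from 7541730 to 16054200, so that 1 count stood for 0.0610 to 0.120 CPM, the unit of counts scaled to library size. CPM values in the text were scaled by the trimmed mean of M-values (TMM) and are given as mean ± SD with n = 2. Ratios of genes with few counts carry an exact binomial interval at 95% confidence, and where a group had 0 counts a floor of 3 counts over the group was used. Both cover counting error only.

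Genes were tested with edgeR 4.0.16 (quasi-likelihood F-test with robust fitting, TMM scaling) in 1 fit of 4 group means over all 8 libraries, with 4 residual degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called when its adjusted p was under 0.05. The 5 comparisons were irradiated against control organoids at day 4 and at day 7, the difference between these effects (irradiation by day), and day 7 against day 4 in control and in irradiated organoids. All adjusted p-values given beside a gene come from this edgeR fit.

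There were 26 gene lists, named for p53 target genes, crypt base stem cell markers, Wnt target genes, fetal-like and regenerative genes, YAP target genes, mitosis genes, DNA replication genes, DNA repair genes, Paneth, goblet, enteroendocrine, tuft and enterocyte markers, prostaglandin genes, the reprogramming factors, interferon-stimulated genes, NF-kB and inflammation genes, senescence genes, sterol synthesis genes, stress response genes, NRF2 target genes, ileal genes, mesenchymal, immune and endothelial markers, and mitochondrial transcripts. Lists with at least 5 tested members (22 of the 26) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, and adjusted over the lists of a comparison. The same test with an estimated correlation and the fry test of limma were alternatives. Camera compares a list with the other genes, which fry does not.

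The genes named in the text follow a rule. For the irradiation effects it takes the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between the libraries compared, without predicted genes and histones. For the other comparisons it takes 5 in each direction. It adds genes named in advance, whatever their values, and up to 4 members of each list past the threshold and 2 of any other. These choices, the lists, the test designs and the first set of alternatives were made before the data were examined.

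The alternatives were the size factors of DESeq2, no filter or a stricter one (at least 5 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) of the deposited TPM for genes with a TPM of at least 1 in 2 libraries, fits of only the groups compared, the replicate number as a block, a fold change of at least 2, libraries without mitochondrial genes, and leaving out each library in turn. A fold change from the TPM fits is on the log2(value + pseudocount) scale and understates changes of low genes. A limma-voom fit with quality weights by group and a fit with the trend on gene length removed were added after seeing the data. All work was done in R 4.3.3.

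The gene test was run on data simulated from the means and sizes of these libraries, with 100 genes changed 2-fold and 100 4-fold. With the same spread in all groups it recovered 70% of the 2-fold and 86% of the 4-fold changes at day 4, and 7.69% of its calls were false. This share was 8.38% for irradiation at day 7, 11.7% for irradiation by day, and over time 11.8% in controls and 7.98% after irradiation. With each group's own measured spread, 33.9% of the day 4 calls were false (76 of 224) and 0 of 147 at day 7. Day 4 replicates lie further apart than the shared spread and day 7 replicates closer. The false share was then 4.69% for irradiation by day, and over time 8.43% in controls and 14.1% after irradiation. In data without change 5 genes and 0 of 21 lists were called, and a 20-gene list raised 1.5-fold was recovered (camera adjusted p = 1.58e-20). Lists of correlated genes were not simulated, so not tested.

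The labels do not say whether libraries of a group came from separate cultures or animals. The p-values measure only the spread between them, which may be technical. The 2 libraries differed by more than sampling noise in every group, which does not show separate samples. Each was kept as one. Chi-square per gene was 15.4 and 1.57 in controls at day 4 and day 7, 18.5 and 1.33 after irradiation. No sample was left out, and groups of 2 are too few to test other splits of the samples. Some genes share reads with near-identical copies (Prl2c2 and Prl2c3, Mup20, Reg1, Ifit1bl2, Gvin1, Gsta1, Lyz1 and Lyz2, Akp3 and Alpi, and the alpha-defensins), and their values are uncertain to that extent.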

Results

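Gene expression was measured by poly-A RNA sequencing in mouse small intestinal organoids that were left untreated or irradiated with 6 Gy of X-rays and collected at day 4 or day 7, with 2 libraries in each of the 4 groups. The total of expected counts per library was 12074600 and 16054200 in controls at day 4, 9119720 and 10538900 in controls at day 7, 9681000 and 11313900 in irradiated organoids at day 4, and 8947390 and 7541730 in irradiated organoids at day 7. Transcripts of the mitochondrial genome took 20.7% and 16.2% of the counts in controls at day 4 and 20.3% and 27.6% in irradiated organoids at day 4, where replicate 2 had the highest share. At day 7 they took 16% and 16.1% in controls and 14.0% and 12.9% after irradiation. Replicates lay further apart at day 4 than at day 7: the biological coefficient of variation was 0.130 and 0.164 in control and irradiated organoids at day 4, and 0.0450 and 0.0398 at day 7. The first 3 principal components held 47.4%, 24.1% and 8.50% of the variance. The series title concerns partial reprogramming, regeneration of the intestine without injury and induction of Ptgs1. These libraries ask what irradiation changed in organoids at 2 times.

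At day 4 irradiated organoids held more transcripts of absorptive enterocytes, of Paneth cells, of p53 target genes and of fetal-like genes than control organoids, and fewer transcripts of dividing cells. All 26 enterocyte markers rose, with a median log2 fold change of 2.78, and 19 of 20 mitosis genes fell, with a median of -0.83. Cdkn1a, the p21 inhibitor of the cell cycle, rose from 72.0 ± 17.2 to 249 ± 35.2 CPM (SD, n = 2; log2 fold change 1.78, adjusted p = 8.23e-05). Lgr5, the marker of crypt base stem cells, fell from 539 ± 66.6 to 179 ± 19.7 CPM (-1.59, adjusted p = 5.42e-06). In total 5130 of the 14063 genes tested were called, 2808 higher and 2322 lower, and 1246 and 413 of them changed at least 2-fold.

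Among called genes with a mean of at least 5 CPM that met the rule's other limits, the largest rise at day 4 was that of Slc5a12, a monocarboxylate transporter, from 2 counts in both control libraries together to 699 in both irradiated ones, a ratio of 532 (counting interval 147 to 4402). Ly6d rose from 5 to 521 counts (ratio 159, 67.5 to 491), Psca from 1 to 199 (ratio 303, 53.8 to 12025) and Zfp365 from 2 to 196 (ratio 149, 40.8 to 1241). Rgs5 rose from 0.536 ± 0.327 to 81.8 ± 27.5 CPM, Slc7a15 from 0.323 ± 0.0255 to 35.4 ± 15.8 CPM and Ifit1bl2 from 0.420 ± 0.249 to 37.8 ± 19.2 CPM. Mup20 rose from 0.469 ± 0.663 to 40.2 ± 30.5 CPM, and its adjusted p was 0.0578 without control replicate 2 of day 4. The largest falls under the same limits were those of Fam129a (10.5 ± 0.850 to 1.14 ± 0.699 CPM, log2 fold change -3.19), Gvin1 (151 ± 27.5 to 16.8 ± 1.22 CPM, log2 fold change -3.17) and Aldh1l2 (30.4 ± 0.661 to 3.41 ± 0.107 CPM, log2 fold change -3.15), a mitochondrial folate enzyme. Grin1, Mab21l3, Adamts15, Grm4 and Fras1 fell by 2.87, 2.68, 2.65, 2.65 and 2.49 on the log2 scale.

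Of the 25 p53 target genes, 22 rose and 0 fell, with a median of 0.90 (camera adjusted p = 6.49e-09, adjusted p = 0.251 with an estimated correlation). Trp53inp1 rose from 29.8 ± 2.26 to 189 ± 32.7 CPM, Ccng1 from 274 ± 0.145 to 808 ± 78.9 CPM, Mdm2, which targets p53 for degradation, from 53.8 ± 2.10 to 138 ± 14.3 CPM, and Bax, which promotes apoptosis, from 24.2 ± 3.82 to 46.8 ± 9.92 CPM. Of the 20 mitosis genes 19 fell and 1 was not called (camera adjusted p = 2.18e-09, adjusted p = 0.291 with an estimated correlation). Mki67 fell from 1068 ± 19.7 to 484 ± 48.1 CPM and Nusap1 by 1.14 on the log2 scale. Of the 20 DNA replication genes 16 fell, with a median of -0.51 (camera adjusted p = 2.73e-06, adjusted p = 0.305 with an estimated correlation). Among them were Mcm6 (-0.69) and Dtl (-0.80). Of the 20 DNA repair genes 13 fell, with a median of -0.63 (camera adjusted p = 1.45e-06, adjusted p = 0.251 with an estimated correlation). Among them were Bard1 (-1.20) and Blm (-0.89). When adjusted over the list alone, 22 p53 targets were higher, and 20 mitosis, 16 replication and 14 repair genes were lower. The 7 senescence genes went both ways, with 3 higher and 2 lower both over all genes and adjusted over the list alone, such as Cdkn2b (1.51) and Cdkn1b (-0.99). Their median was -0.29, their mean 0.55 and the camera test pointed up without passing (adjusted p = 0.980).

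Among the cell type markers, the 26 enterocyte genes had the highest camera rank (camera adjusted p = 3.87e-15, adjusted p = 0.251 with an estimated correlation). Apob, part of the lipoproteins that carry fat, rose from 678 ± 113 to 2511 ± 98.2 CPM, Alpi, the intestinal alkaline phosphatase, from 13.1 ± 2.51 to 211 ± 62.6 CPM, Apoa4 from 109 ± 39.2 to 1507 ± 849.9 CPM and the glucose transporter Slc2a2 from 19.2 ± 0.373 to 214 ± 54.9 CPM. Of the 17 Paneth markers, 12 rose and 0 fell, with a median of 2.5 (camera adjusted p = 1.12e-06, adjusted p = 0.251 with an estimated correlation). Mmp7 rose from 7.73 ± 4.98 to 125 ± 11.9 CPM and lysozyme Lyz1 from 208 ± 15.2 to 941 ± 368 CPM. All 4 ileal genes measured rose, too few for a list test, with a median of 4.10 (Slc51a 5.0, Slc51b 4.34). Of the 10 tuft cell markers 6 fell and 1 rose, with a median of -1.92 (camera adjusted p = 0.00555, adjusted p = 0.251 with an estimated correlation). Among them were Lrmp (-3.25), Avil (-2.66) and Dclk1, which fell from 2.99 ± 0.953 to 0.596 ± 0.235 CPM. DESeq2 called 4 tuft markers where edgeR called 7. Without control replicate 2 of day 4 the tuft list missed the threshold (adjusted p = 0.0566), and without control replicate 1 or irradiated replicate 1 of day 4 Dclk1 did (highest adjusted p = 0.0594). Of the 25 enteroendocrine markers 7 rose, with a median of 0.41 (camera adjusted p = 0.0249, adjusted p = 0.540 with an estimated correlation). Examples are Cpe (1.62) and Nts (1.94). Chga went from 95.9 ± 49.9 to 197 ± 3.34 CPM without passing (adjusted p = 0.0698). The list call was lost without replicate 2 of either day 4 group (highest adjusted p = 0.326), and the median was 0.64 without control replicate 1 and 0.13 without control replicate 2 of day 4.

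Markers of crypt base stem cells moved apart: 10 of 20 fell and 3 rose, with a median of -0.15 and no list call (camera adjusted p = 0.0628). Lgr5 fell, as given above, and Olfm4 fell from 708 ± 21.3 to 337 ± 122 CPM. Tnfrsf19 rose from 6.33 ± 1.89 to 25.9 ± 1.53 CPM and Ascl2 was not called (0.25, adjusted p = 0.397). The call of Olfm4 was lost without control replicate 2 of day 4 (adjusted p = 0.0522). Of the 10 Wnt target genes 5 rose and 1 fell, without a list call (median 0.61, camera adjusted p = 0.0933). Among them were Sp5 (1.66) and Apcdd1 (1.16). Goblet cell markers also went both ways, with 6 of 17 higher, such as Zg16 (3.94) and Guca2a (2.39), and 2 lower. The mucin Muc2 was at 530.2 ± 72.3 and 529 ± 178 CPM. Their median was -0.00, their mean 0.59, and the camera test pointed up without passing (adjusted p = 0.328). Among the cell type markers, adjusted over the list alone, 26 enterocyte, 15 Paneth, 4 ileal, 5 enteroendocrine and 7 goblet markers were higher, 7 tuft markers were lower, 3 stem markers were higher and 10 lower, and 5 Wnt targets were higher and 2 lower.

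Of the 21 fetal-like and regenerative genes measured, 19 rose and 0 fell, with a median of 2.99 (camera adjusted p = 2.44e-08, adjusted p = 0.251 with an estimated correlation). Clu, the marker of revival stem cells, rose from 7.37 ± 5.25 to 133 ± 71.4 CPM (adjusted p = 0.00741), Ly6a (Sca-1) from 2.03 ± 0.627 to 26.6 ± 13.4 CPM (adjusted p = 2.49e-04) and Anxa1 from 7.36 ± 3.94 to 148 ± 98.5 CPM. Without control replicate 2 of day 4 the adjusted p of Anxa1 was 0.0528. Of the 19 YAP target genes 12 rose and 2 fell, with a median of 1.05 (camera adjusted p = 0.00170, adjusted p = 0.251 with an estimated correlation). Among them were Ptpn14 (3.35), F3 (1.92) and Arhgef17 (-1.55). The YAP median was 1.77 without control replicate 2 and 1.59 without irradiated replicate 2 of day 4. Of the 16 NF-kB and inflammation genes 13 rose, with a median of 1.98 (camera adjusted p = 1.45e-06, adjusted p = 0.125 with an estimated correlation). The chemokine Cxcl16 rose from 7.90 ± 2.37 to 41.0 ± 10.9 CPM and Ccl20 from 1.66 ± 1.14 to 11.8 ± 0.508 CPM. Of the 22 interferon-stimulated genes 11 rose, with a median of 1.86 (camera adjusted p = 5.06e-04, adjusted p = 0.469 with an estimated correlation). Their summed level was 205 CPM in irradiated replicate 1 and 618 CPM in replicate 2, the library with the highest mitochondrial share, and without replicate 2 the median was 0.67 (adjusted p = 0.0339). DESeq2 called 16 and limma-voom 6 of the interferon genes. Ddx58 (RIG-I) rose from 16.1 ± 0.534 to 45.8 ± 17.0 CPM. Immune markers summed to 11.6 and 13.8 CPM in irradiated organoids at day 4 and to 4.69 to 7.34 CPM in the other 6 libraries, and 3 of the 4 tested rose as well. Which cells the rises of NF-kB and interferon genes over control came from was not tested. Of the 15 NRF2 target genes 8 rose and 1 fell, with a median of 0.86 (camera adjusted p = 7.26e-04, adjusted p = 0.209 with an estimated correlation). Among them were Srxn1 (1.79) and Gstm1 (1.45). Without irradiated replicate 1 of day 4 their median was 0.50. Adjusted over the list alone, 19 fetal-like genes were higher and 1 lower, 12 YAP targets were higher and 2 lower, 15 NF-kB, 13 interferon and 10 NRF2 genes were higher, and 1 NRF2 gene was lower.

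Of the 14 prostaglandin genes tested, 6 rose and 1 fell, with a median of 0.53 (camera adjusted p = 0.0224, adjusted p = 0.251 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, rose from 0.420 ± 0.354 to 7.72 ± 4.14 CPM (log2 fold change 4.05, adjusted p = 0.00156), Hpgd, which breaks prostaglandins down, from 20.7 ± 2.84 to 118 ± 0.281 CPM, and the transporter Slco2a1 from 5.81 ± 0.459 to 19.9 ± 1.25 CPM. Ptgs1, the constitutive cyclooxygenase named in the series title, had 3 counts in the 2 control libraries and 6 in the 2 irradiated ones, a ratio of 3.04 (counting interval 0.650 to 18.8), so a difference was not detectable at this depth (edgeR with no filter, adjusted p = 0.583). The receptor Ptger4 was at 6.08 ± 0.885 and 8.12 ± 1.60 CPM (adjusted p = 0.173). Of the reprogramming factors, Pou5f1 had 4 counts and Sox2 had 1 count in all 8 libraries together. Klf4 (-0.41, adjusted p = 0.0732) and Myc (-0.36, adjusted p = 0.0637) were not called by edgeR, though both had an unadjusted p under 0.05, 0 were called by DESeq2 and 1 by limma-voom. For these lists, adjusted over the list alone, 8 prostaglandin genes were higher and 1 lower, and both Klf4 and Myc were lower.

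Sterol synthesis genes fell in 15 of 22 cases and rose in 1, with a median of -0.51 (camera adjusted p = 3.85e-04, adjusted p = 0.409 with an estimated correlation). Acat2 fell from 168 ± 32.4 to 90.2 ± 2.49 CPM and Lss from 213 ± 55.0 to 105 ± 4.67 CPM. Without control replicate 1 of day 4 the median was -0.27. Of the 16 stress response genes 8 fell and 2 rose, with a median of -0.36 (camera adjusted p = 0.0263, adjusted p = 0.251 with an estimated correlation), a call lost without irradiated replicate 1 of day 4 (adjusted p = 0.0867). Those with the smallest p were Asns (-1.17), Mthfd2 (-1.28), Psat1 (-1.09) and Shmt2 (-0.96), which make amino acids or 1-carbon units. Mitochondrial transcripts had a median of 0.53, with 2 of 13 higher (camera adjusted p = 0.0224, adjusted p = 0.540 with an estimated correlation), a call lost without replicate 2 of either day 4 group (highest adjusted p = 0.324), with medians of 0.32 without the control and 0.28 without the irradiated one, and of 0.83 without irradiated replicate 1. Adjusted over the list alone, 1 sterol gene was higher and 15 lower, 2 stress genes were higher and 9 lower, and 0 mitochondrial transcripts were called. Of 4 immune markers 3 rose, such as Csf1r (2 to 32 counts, ratio 24.4, 6.21 to 209.8). Of 3 endothelial markers 1 rose (Tek, 3.58) and 1 fell (Egfl7, -2.21), with the same counts for both of these lists adjusted over the list alone. Egfl7 lost its call without replicate 2 of either day 4 group (highest adjusted p = 0.0704). Of 5 mesenchymal markers 0 were called by edgeR, by DESeq2 or by limma-voom, nor had any an unadjusted p under 0.05, and 0 were called adjusted over the list alone (median -0.60, camera adjusted p = 0.699).

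**Figure D1:**
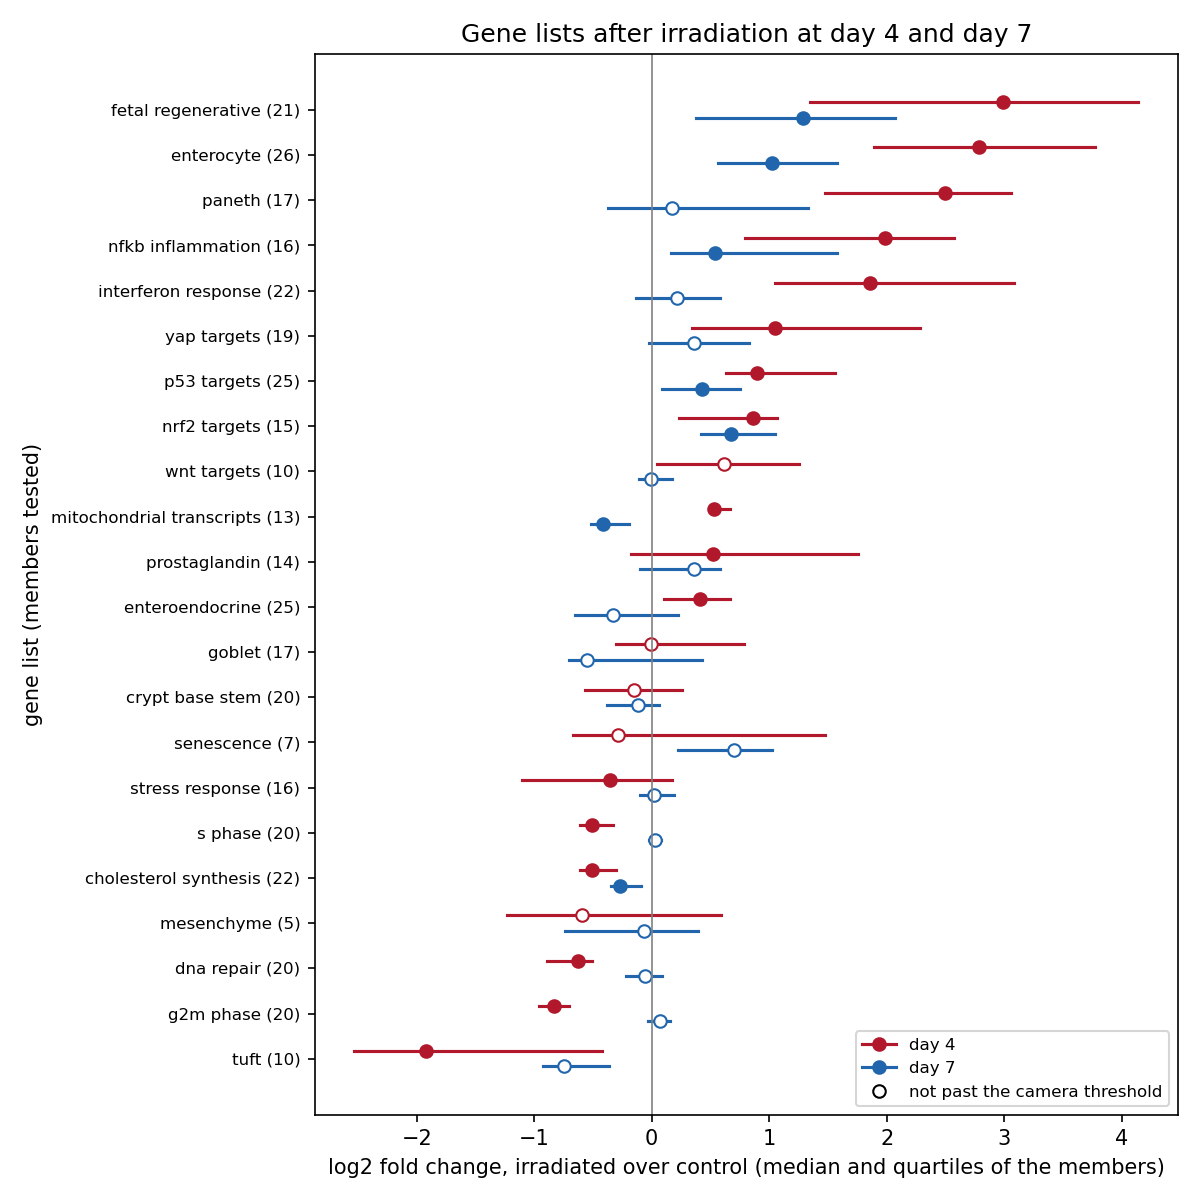
Median (point) and quartiles (line) of the edgeR log2 fold changes, irradiated over control, of the members of 22 gene lists at day 4 (red) and day 7 (blue), with the number of members tested in brackets. Filled points passed camera with the preset correlation. Enterocyte markers had a median of 2.78 at day 4 and 1.02 at day 7, and mitosis genes of -0.83 and 0.07.

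Camera called 17 of the 22 lists at day 4 with the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05. Fry called 17. With each group's spread 33.9% of simulated calls were false, but few genes were changed, so the share need not hold here. A fit of the day 4 libraries alone called 3228 genes and limma-voom with weights by group 3562. Of the 105 gene results named by the rule and called at day 4, 93 were called in every fit that left out 1 library. Scaled as log2(TPM + 1), where the median of all genes shifted by -0.17, 1104 genes were called higher and 1732 lower. Every called list kept the sign of its median there, also relative to the shift.

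At day 7 some genes of enterocytes, p53 targets, fetal-like genes and NRF2 targets were still higher in irradiated than in control organoids, and mitosis genes were near the control level. Of the 26 enterocyte markers 12 rose, of 25 p53 targets 11, of 21 fetal-like genes 6 and of 15 NRF2 targets 8, and 0 of any of these fell. The enterocyte list had a median log2 fold change of 1.02. Camera called these 4 lists with the preset correlation and 0 of them with an estimated one (adjusted p = 0.456, 0.490, 0.456 and 0.0786), and fry called the NRF2 list (adjusted p = 9.51e-04) and not the first 3 (0.0582, 0.0655 and 0.0582). Lgr5 fell from 535 ± 3.13 to 292 ± 3.67 CPM (SD, n = 2; -0.87, adjusted p = 0.00159) and Olfm4 from 1587 ± 40.6 to 847 ± 25.6 CPM (adjusted p = 0.0421). Cdkn1a was at 47.2 ± 2.83 and 75.1 ± 0.412 CPM (0.67, adjusted p = 0.0423), and Mdm2 at 51.9 ± 0.0677 and 50.6 ± 1.74 CPM (-0.04, adjusted p = 0.857). In total 1216 genes were called, 661 higher and 555 lower, of which 234 and 118 changed at least 2-fold. A fit of the day 7 libraries alone called 4732 genes and limma-voom with weights by group 4120, against 3228 and 3562 at day 4. Both called more genes at day 7.

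Among the largest rises of genes with a mean of at least 5 CPM that met the rule's other limits, Prl2c2 had 0 counts in both control libraries and 215 in the irradiated ones, at least 79.9-fold higher against a floor of 3 counts over the group, and its near-identical relative Prl2c3 rose from 0.629 ± 0.282 to 19.7 ± 3.41 CPM. Mup20 rose from 0.813 ± 0.369 to 55.7 ± 4.75 CPM, Anxa10 from 9.84 ± 1.42 to 84.2 ± 3.92 CPM, Reg1 from 2.32 ± 0.673 to 30.3 ± 1.48 CPM and the sugar transporter Slc5a4b from 2.44 ± 0.714 to 24.4 ± 0.206 CPM. Ctse, a protease of gastric cells, rose from 0.606 ± 0.206 to 10.8 ± 0.235 CPM and Clca1, secreted by goblet cells, from 0.996 ± 0.802 to 12.9 ± 0.639 CPM. Under the same limits, the largest falls were those of P4ha2 (17.2 ± 0.127 to 2.40 ± 0.356 CPM, log2 fold change -2.85), which hydroxylates collagen, Smtnl2 (10.2 ± 2.11 to 1.5 ± 0.0957 CPM, log2 fold change -2.77) and Rgs11 (17.0 ± 0.311 to 3.83 ± 0.367 CPM, log2 fold change -2.15). The noncoding RNA Malat1 fell from 2164 ± 91.4 to 717 ± 18.8 CPM and Kcnq1ot1, antisense to Kcnq1, by 1.93 on the log2 scale. Vldlr, Stc2 and Mrpl23 fell by 1.68, 1.63 and 1.79.

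Of the 26 enterocyte markers, Alpi rose from 34.4 ± 4.08 to 119 ± 6.66 CPM and Krt20, a keratin of differentiated cells, from 30.2 ± 2.79 to 114 ± 1.24 CPM (camera adjusted p = 8.28e-11, adjusted p = 0.456 with an estimated correlation). Apoa4 was at 153 ± 3.78 and 274 ± 15.1 CPM (adjusted p = 0.344). The p53 targets had a median of 0.43 (camera adjusted p = 2.31e-05, adjusted p = 0.490 with an estimated correlation). Examples are Ccng1 (0.61), Bax (0.90) and Eda2r (1.15). The fetal-like genes had a median of 1.28 (camera adjusted p = 2.85e-07, adjusted p = 0.456 with an estimated correlation). Ly6d rose from 0.920 ± 0.390 to 6.67 ± 1.10 CPM and Il1rn from 5.30 ± 0.859 to 32.3 ± 1.72 CPM, and DESeq2 called 10 and limma-voom 4 of the list. Clu went from 29.0 ± 1.18 to 113 ± 0.603 CPM (adjusted p = 0.112). It, Ly6a (0.25) and Anxa1 (1.72) were not called. The shared spread was wider than day 7's, so Clu and Apoa4 may still be higher. The NRF2 targets had a median of 0.68 (camera adjusted p = 1.01e-07, adjusted p = 0.0786 with an estimated correlation). Gstm1 rose from 469 ± 13.2 to 1205 ± 37.6 CPM and the quinone reductase Nqo1 from 24.6 ± 0.868 to 56.6 ± 1.55 CPM. At day 7, adjusted over the list alone, 18 enterocyte, 15 p53, 13 fetal-like and 13 NRF2 genes were higher and 1 p53 target was lower.

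Sterol synthesis genes had a median of -0.27, with 3 of 22 lower (camera adjusted p = 0.0146, adjusted p = 0.798 with an estimated correlation). Examples are Stard4 (-0.45) and Lss (-0.62). 5 were lower adjusted over the list alone. Without irradiated replicate 1 of day 7 the adjusted p was 0.0650. NF-kB genes had a median of 0.54, with 2 of 16 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.0190, adjusted p = 0.440 with an estimated correlation). Examples are Cxcl16 (1.77) and Duox2 (2.7). Without irradiated replicate 2 of day 7 the adjusted p was 0.101, and without control replicate 1 the median was 0.35. Mitochondrial transcripts had a median of -0.41 (camera adjusted p = 0.0495, adjusted p = 0.815 with an estimated correlation), a call lost without replicate 2 of either day 7 group (highest adjusted p = 0.202). Of the 13, 0 were called by edgeR or adjusted over the list alone, 5 had an unadjusted p under 0.05, and 3 were called by DESeq2 and 0 by limma-voom. The mitochondrial share of the counts was 14.0% and 12.9% after irradiation against 16% and 16.1% in controls.

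The other lists were not called at day 7. Mitosis genes had a median of 0.07 (camera adjusted p = 0.754), with 2 of 20 lower, Mki67 from 930.1 ± 0.816 to 724 ± 9.46 CPM and Cenpf (-0.44). The DNA repair list had 1 of 20 lower, Atm (-0.49; camera adjusted p = 0.273). Of 20 replication genes, 10 Wnt targets, 22 interferon genes and 3 endothelial markers, 0 were called by edgeR, DESeq2 or limma-voom, 0 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone (camera adjusted p = 0.764, 0.754 and 0.634 for the first 3, medians 0.03, -0.01 and 0.22, endothelial median 0.12, mean -0.05). For Wnt targets the median was below 0 and the test pointed up. Stem cell markers had 6 of 20 lower and 1 higher (camera adjusted p = 0.0716), with Nrn1, from 6.82 ± 0.235 to 0.505 ± 0.137 CPM. Ascl2 was not called (0.51, adjusted p = 0.120). Paneth markers had 1 of 17 higher, Pnliprp2 (2.04), and 1 lower, Habp2 (-0.81; camera adjusted p = 0.754), and Lyz1 was not called (-0.37). Goblet markers had 4 of 17 higher, such as Zg16 (2.78), and 2 lower, such as Agr2 (-0.88), with a median of -0.55, a mean of 0.07 and a test pointing down (camera adjusted p = 0.458). Muc2 was not called (-0.71). Enteroendocrine markers had 3 of 25 higher, such as Cck (1.00), and 3 lower, such as Pcsk1 (-0.92; camera adjusted p = 0.172), with Chga not called (0.27) and 3 called by DESeq2 and by limma-voom, and tuft markers 1 of 10 lower, Kctd12 (-0.90; camera adjusted p = 0.0657), with Dclk1 at 11 and 6 counts.

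Prostaglandin genes had 3 of 14 higher at day 7 (median 0.36, camera adjusted p = 0.0716). Ptgs2 rose from 2.61 ± 1.48 to 11.0 ± 0.281 CPM (2.10, adjusted p = 0.0403) and Hpgd from 27.9 ± 0.523 to 49.6 ± 5.10 CPM. Ptger4 was not called (0.42, adjusted p = 0.239). Ptgs1 had 2 counts in controls and 8 after irradiation, a ratio of 4.46 (counting interval 0.890 to 43.1), which was not detectable as a difference at this depth (edgeR with no filter, adjusted p = 0.563). YAP targets had 2 of 19 higher, Areg (1.56) and F3 (2.29; median 0.36, camera adjusted p = 0.0817), senescence genes 1 of 7 higher, Plaur (1.45; median 0.70, camera adjusted p = 0.273), and stress response genes 1 of 16 higher, Herpud1 (0.69; median 0.02, camera adjusted p = 0.634). Of 4 ileal genes 1 rose, Slc51a (2.52), with a median of 2.05. Klf4 and Myc were not called by edgeR, DESeq2 or limma-voom (-0.51 and -0.03), with 1 of them at an unadjusted p under 0.05. The same tools called 0 of 4 immune markers (median 0.01) and 0 of 5 mesenchymal ones (median -0.07, camera adjusted p = 0.645), with 1 of each at an unadjusted p under 0.05. Adjusted over the list alone, the counts higher and lower were 0 and 2 for mitosis, 0 and 1 for repair, 3 and 8 for stem, 1 and 2 for Paneth, 4 and 5 for goblet, 3 and 3 for enteroendocrine, 0 and 1 for tuft, 3 and 0 for prostaglandin, 2 and 1 for YAP, 2 and 0 for senescence and ileal, 1 and 0 for stress genes, 0 and 1 for the reprogramming factors, and 0 for immune and mesenchymal markers.

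Without either control library of day 7 the edgeR count at day 7 was 110 (replicate 1) or 122 (replicate 2), without either irradiated one 165 or 105, and without either irradiated library of day 4 it was 2311 or 2341. Of the 60 gene results named by the rule and called at day 7, 16 kept their call in every such fit. Among them were Ly6d, Krt20, Gstm1, Srxn1, Malat1, Kcnq1ot1, Ctse, Clca1, Prl2c3, Slc5a4b, Nrn1, Pnliprp2, F3 and Zg16. Lgr5 missed the threshold only without irradiated replicate 2 of day 7 (adjusted p = 0.0553). Camera called 7 of 22 lists with the preset correlation and 0 with an estimated one, where 2 had an unadjusted p under 0.05, and fry called 4. Without irradiated replicate 1 of day 4 camera called 11. On the log2(TPM + 1) scale, where the median of all genes shifted by 0.12, 316 genes were called higher and 71 lower, and with no filter 1374 and 670. The median log2 fold change was 0.12 in the shortest and -0.22 in the longest 10% of genes. With this length trend removed 771 genes were called, 687 of them shared. The gene values given, as for Mki67 and Atm, are not corrected for it.

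**Figure D2:**
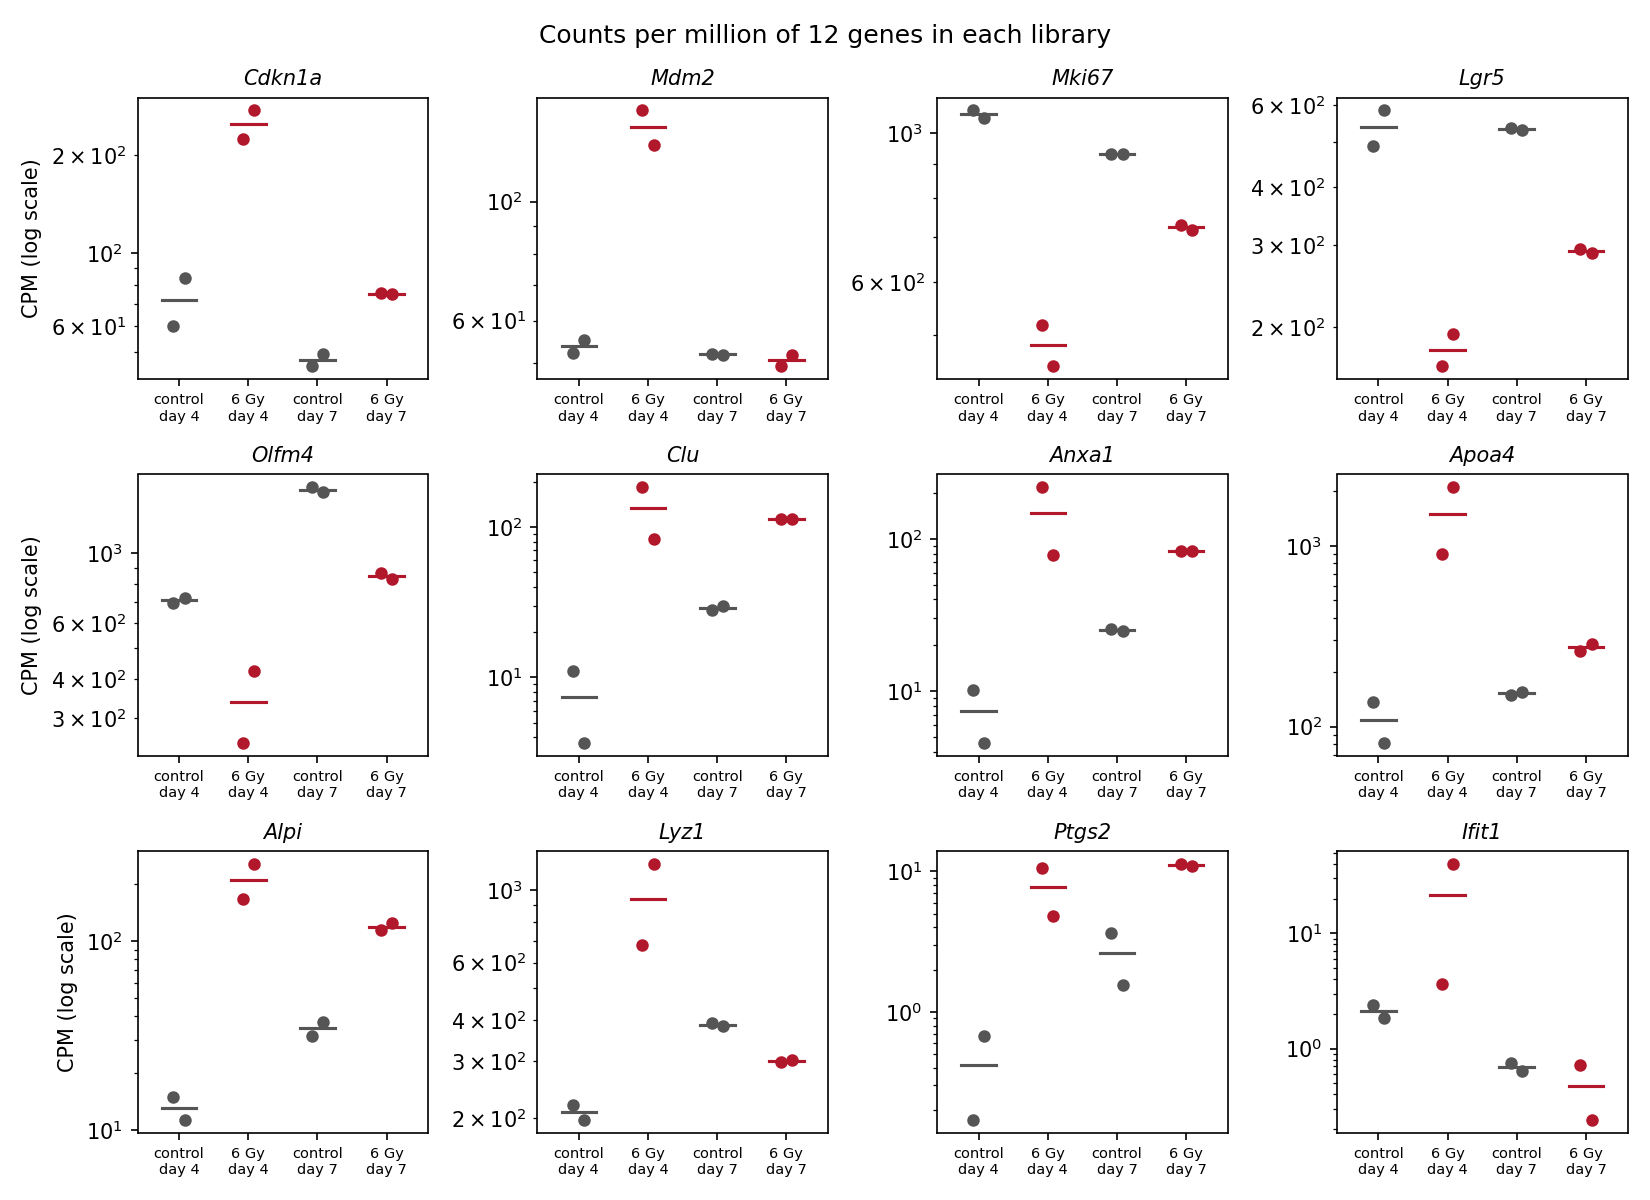
CPM on a log axis of 12 genes in each of the 8 libraries, for control (grey) and irradiated (red) organoids at day 4 and day 7. Points are libraries and bars the mean of 2. Mki67 lay at a mean of 1068 in controls and 484 in irradiated organoids at day 4, and the 2 irradiated libraries of day 4 lie far apart for Ifit1.

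Whether the effect of irradiation differed between the days was tested as the effect at day 7 less that at day 4. Mitosis genes had a difference of 0.84 (median log2), with 18 of 20 called, since 19 fell at day 4 and 2 at day 7 (camera adjusted p = 5.88e-12, adjusted p = 0.322 with an estimated correlation). Enterocyte markers had a difference of -1.80, with 16 of 26 called (camera adjusted p = 2.52e-11, adjusted p = 0.322 with an estimated correlation), and Paneth markers of -1.65, with 7 of 17 called (camera adjusted p = 2.37e-06, adjusted p = 0.322 with an estimated correlation), so both effects were smaller at day 7. The Paneth difference was -3.01 without control replicate 1 of day 4. For p53 targets the difference was -0.51, with 9 of 25 called (camera adjusted p = 3.25e-05, adjusted p = 0.374 with an estimated correlation), and for Mdm2 it was -1.39 (adjusted p = 7.21e-04). Without control replicate 2 of day 4 the p53 difference was -0.77. In total 1422 genes were called, 647 with a higher and 775 with a lower effect at day 7. Of these, 1278 were called at day 4, of which 694 had risen and 581 fallen with a smaller effect at day 7.

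Among called genes with a mean of at least 5 CPM that met the rule's other limits, the largest differences were those of Prex2 (3.04), Dmbt1 (2.60), Aldh1l2 (2.37), Matn2 (2.29) and Gvin1 (2.25) upward, and of Gal3st2 (-8.72), Ifit1bl2 (-5.15), Slc7a15 (-5.08), Cubn (-4.97) and Npl (-4.75) downward. The 5 downward calls were each lost without control replicate 2 of day 4 or any of the 4 libraries of day 7 (adjusted p up to 0.196, for Gal3st2). Cubn, an uptake receptor of enterocytes, went from 0.907 ± 0.163 to 81.5 ± 42.1 CPM at day 4 and from 1.56 ± 0.390 to 4.59 ± 0.143 CPM at day 7, and Dmbt1 from 233 ± 57.0 to 51.8 ± 13.5 and from 99.8 ± 2.06 to 134 ± 3.88 CPM. Among the genes named in advance, the difference was called for Cdkn1a (-1.12), Ccng1 (-0.95), Lgr5 (0.72), Mki67 (0.78), Ly6a (-3.49), Lyz1 (-2.55) and Alpi (-2.24), and not for Olfm4 (0.17), Bax (-0.05), Clu (-2.28), Anxa1 (-2.67), Apoa4 (-2.95) or Ptgs2 (-1.95, adjusted p = 0.177). Of these 7 calls, that of Ccng1 was kept in every fit without 1 library (adjusted p up to 0.0379). The call of Cdkn1a was lost without any library of day 7 or irradiated replicate 2 of day 4 (adjusted p up to 0.111), that of Lgr5 without any library of day 7 (up to 0.0848), and that of Lyz1 without control replicate 2 of day 4 or any library of day 7 (up to 0.0609). The call of Ly6a was lost without control replicate 2 of day 4, control replicate 1 of day 7 or either irradiated library of day 7 (up to 0.0566), that of Alpi without control replicate 2 or either irradiated library of day 7 (up to 0.0588), and that of Mki67 without either control of day 7 (up to 0.0541). Of the 71 gene results named by the rule and called for this difference, 25 kept their call in every such fit and 46 lost it in 1 or more.

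Of the other lists, replication genes had a difference of 0.53 with 7 of 20 called (camera adjusted p = 4.09e-07, adjusted p = 0.322 with an estimated correlation) and repair genes of 0.63 with 3 of 20 (camera adjusted p = 4.47e-06, adjusted p = 0.322 with an estimated correlation). Fetal-like genes had a difference of -1.14 with 5 of 21 called (camera adjusted p = 1.27e-04, adjusted p = 0.374 with an estimated correlation) and NF-kB genes of -0.75 with 2 of 16 (camera adjusted p = 9.18e-04, adjusted p = 0.322 with an estimated correlation). Interferon genes had a difference of -1.42 with 1 of 22 called (camera adjusted p = 0.00239, adjusted p = 0.511 with an estimated correlation), which was lost without irradiated replicate 2 of day 4 (adjusted p = 0.195). Mitochondrial transcripts differed by -0.95 with 3 of 13 called (camera adjusted p = 9.47e-04, adjusted p = 0.448 with an estimated correlation), enteroendocrine markers by -0.72 with 2 of 25 (camera adjusted p = 0.00283, adjusted p = 0.459 with an estimated correlation), and goblet markers by -0.53 with 3 of 17 (camera adjusted p = 0.00982, adjusted p = 0.322 with an estimated correlation), lost without control replicate 2 of day 4 (adjusted p = 0.0551). Stress response genes had a difference of 0.30 with 6 of 16 called (camera adjusted p = 0.00239, adjusted p = 0.322 with an estimated correlation), and sterol genes of 0.24 with 2 of 22 (camera adjusted p = 0.0142, adjusted p = 0.520 with an estimated correlation), lost without replicate 1 of either day 4 group (highest adjusted p = 0.742). Leaving out 1 library of day 4 also moved these differences by over 1.5 times: without control replicate 1 the sterol difference was -0.05, and without control replicate 2 those of enteroendocrine, goblet and sterol genes were -0.33, -0.30 and 0.44. Without irradiated replicate 1 the fetal-like difference was -0.64, and without irradiated replicate 2 those of repair, interferon, mitochondrial and goblet genes were 0.41, -0.53, -0.61 and -0.32. For this difference, adjusted over the list alone, 20 mitosis, 14 replication, 8 repair, 8 stress and 2 sterol genes had a higher effect at day 7, and 21 enterocyte, 9 Paneth, 12 p53, 7 fetal-like, 4 NF-kB, 4 goblet, 5 mitochondrial, 1 enteroendocrine, 1 stress and 0 interferon genes a lower one.

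Beyond these 14 lists camera called no other of the 22. The tuft (0.72, adjusted p = 0.0578), YAP (-0.53, 0.0638), Wnt (-0.54, 0.0973), prostaglandin (-0.49, 0.104) and NRF2 lists (0.00, 0.784) did not pass. Nor did the stem cell markers (0.03, mean -0.07, 0.461), senescence genes (0.19, mean -0.02, 0.374) and mesenchymal markers (-0.20 with a test direction upward, 0.941). Among the lists too small for camera, the difference was called for 1 of 4 ileal genes, Slc51b (-3.37), and by edgeR, DESeq2 and limma-voom for 0 of 4 immune (median -1.66), 3 endothelial (-2.47) and 2 reprogramming genes (0.11), with 1, 1 and 0 at an unadjusted p under 0.05. The call of Slc51b was lost without control replicate 2 of day 4 or any library of day 7 (adjusted p up to 0.0897). Of these, 2 ileal genes and 1 immune marker were lower when adjusted over the list alone. With an estimated correlation 0 lists passed, 2 had an unadjusted p under 0.05, and fry called 12. The 2 irradiation comparisons share no library. Among their calls 492 genes were higher at both days, against 132 for independent lists, 299 were lower at both, against 91.6, and 34 went opposite ways. Without either day 7 control the count for irradiation by day was 244 or 270, without either irradiated library of day 7 it was 264 or 251, without irradiated replicate 1 of day 4 it was 2718, and without control replicate 2 of day 4 it was 882. On the log2(TPM + 1) scale, where the median of all genes shifted by 0.26, 184 genes were called higher and 124 lower.

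In control organoids, the comparison of day 7 with day 4 gives the change over time without irradiation. Markers of enteroendocrine cells fell: 10 of 25 were lower at day 7 and 0 higher, with a median log2 fold change of -1.10 (camera adjusted p = 2.16e-12, adjusted p = 0.269 with an estimated correlation). The hormone gene Cck fell from 47.2 ± 3.53 to 9.28 ± 1.29 CPM (SD, n = 2; adjusted p = 1.26e-04), and Gcg, Tac1 and Pcsk1 fell by 2.09, 2.14 and 1.49 on the log2 scale. Stem cell markers rose: 8 of 20 were higher and 0 lower, with a median of 0.42 (camera adjusted p = 2.17e-08, adjusted p = 0.139 with an estimated correlation). Examples are Olfm4, from 708 ± 21.3 to 1587 ± 40.6 CPM, Tnfrsf19 (2.0) and Ascl2 (1.07). Lgr5 was at 539 ± 66.6 and 535 ± 3.13 CPM. Of the 10 Wnt target genes 5 rose and 0 fell, with a median of 0.62 (camera adjusted p = 1.65e-05, adjusted p = 0.230 with an estimated correlation), Axin2 from 128 ± 0.374 to 251 ± 12.9 CPM. In total 382 genes were called, 176 higher and 206 lower.

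Goblet markers fell in 4 of 17 cases and rose in 0, with a median of -0.52 (camera adjusted p = 3.39e-05, adjusted p = 0.230 with an estimated correlation), Muc2 from 530.2 ± 72.3 to 177 ± 3.17 CPM and Agr2 by 0.96 on the log2 scale. Tuft markers had a median of -0.84 with 1 of 10 lower, Kctd12 (-0.84, camera adjusted p = 5.38e-06, adjusted p = 0.139 with an estimated correlation). Dclk1 was not called (-2.40, adjusted p = 0.0546). Smaller shifts passed camera for sterol genes (median -0.26, 1 of 22 lower, camera adjusted p = 0.00177, adjusted p = 0.705 with an estimated correlation), p53 targets (-0.26, 3 of 25 lower, camera adjusted p = 0.0185, adjusted p = 0.705 with an estimated correlation), Paneth markers (0.18, 1 of 17 higher, camera adjusted p = 0.0425, adjusted p = 0.705 with an estimated correlation), fetal-like genes (0.37, 0 higher and 1 of 21 lower, Anxa2 at -0.64, camera adjusted p = 0.0426, adjusted p = 0.705 with an estimated correlation) and replication genes (0.13, camera adjusted p = 0.0475, adjusted p = 0.717 with an estimated correlation). Of the replication genes 0 were called by edgeR, DESeq2 or limma-voom, with 4 at an unadjusted p under 0.05. Each of these 5 calls was lost when certain libraries were left out: the sterol call without control replicate 1 of day 4 (adjusted p = 0.820), the p53 call without control replicate 2 of day 4 (0.262), the Paneth call without replicate 2 of either control group (up to 0.869), and the fetal-like call without either control of day 4, control replicate 2 of day 7 or either irradiated library of day 7, and the replication call without control replicate 1 of day 4 or any library of day 7 (up to 0.294 and 0.244). Without control replicate 1 of day 4 the medians were -0.02 for sterol, 0.97 for Paneth and 0.09 for replication genes, and without control replicate 2 they were -0.43 for sterol, -0.15 for Paneth and -0.09 for p53. Adjusted over the list alone, the counts higher and lower were 1 and 15 for enteroendocrine, 13 and 0 for stem, 6 and 1 for Wnt, 0 and 9 for goblet, 0 and 2 for tuft, 0 and 2 for sterol, 3 and 8 for p53, 3 and 1 for Paneth, 3 and 1 for fetal-like and 4 and 0 for replication genes.

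The other 12 lists did not pass camera in controls. Of 19 YAP targets Ptpn14 rose (1.84) and Crim1 fell (-0.62; list median 0.03, adjusted p = 0.473, with a test direction downward). Of 26 enterocyte markers Alpi rose and Npc1l1 fell (-0.81; list median 0.09, adjusted p = 0.440), and of 14 prostaglandin genes Pla2g4a rose (1.19) and Slco2a1 fell (-1.09; list median 0.31, adjusted p = 0.205). Of 16 stress genes Mthfd2 fell (-0.61; list median -0.07, adjusted p = 0.384). These 7 calls were each lost without either control of day 7, and all but that of Pla2g4a also without control replicate 2 of day 4 or either irradiated library of day 7 (adjusted p up to 0.353, for Mthfd2, whose log2 fold change was -0.39 without control replicate 2 of day 4). Those of Ptpn14, Alpi and Slco2a1 were lost without control replicate 1 of day 4 as well. With the median and the camera adjusted p of each list in brackets, edgeR called 0 mitosis (-0.05, 0.268), repair (0.01, 0.700), interferon (-0.73, 0.111), NF-kB (-0.30, 0.641), senescence (-0.23, 0.258) and NRF2 genes (0.03, 0.229), mesenchymal markers (-1.05, 0.370) or mitochondrial transcripts (-0.31, 0.111). At an unadjusted p under 0.05 these 8 lists had 2, 2, 1, 2, 1, 6, 1 and 1 genes, and DESeq2 called 2 NRF2 genes and 0 of the others, limma-voom 0. In controls, adjusted over the list alone, the counts higher and lower were 1 and 3 for YAP, 2 and 2 for enterocyte, 4 and 3 for prostaglandin, 1 and 3 for stress, 4 and 1 for NRF2, 0 and 1 for senescence and 0 and 1 for mesenchymal genes, and 0 for the rest. Of the 2 reprogramming factors tested Klf4 fell (-0.74), a call lost without control replicate 2 of day 4 or any library of day 7 (adjusted p up to 0.327), and both were lower adjusted over the list alone. EdgeR, DESeq2 and limma-voom called 0 of 4 immune (median 0.46), 3 endothelial (-0.69) and 4 ileal genes (0.31), with 0, 0 and 1 at an unadjusted p under 0.05.

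Among genes with a mean of at least 5 CPM that met the rule's other limits, the largest rises in controls were those of Akp3, an alkaline phosphatase close to Alpi, from 1.97 ± 0.110 to 13.1 ± 0.113 CPM, Nkd1, an inhibitor of Wnt signalling (2.55), Slc14a1 (2.36), Pcdh8 (2.34) and Prelp (2.15). Alpi itself rose by 1.42 (log2). Under the same limits, the largest falls were those of Pappa2 (-2.60), Grm4 (-2.38), Cck (-2.35), C1rl (-2.29) and Adamts15 (-2.24). Of the 41 gene results named by the rule and called here, 7 kept their call in every fit without 1 library: Akp3, Slc14a1, Prelp, Cck, Pcsk1, Agr2 and Tnfrsf19. A fit of the control libraries alone called 620 genes and limma-voom with weights by group 858. Without either day 7 control the count of calls was 31 or 17, without either irradiated library of day 7 it was 102 or 105, without either irradiated library of day 4 it was 1220 or 1234, and without control replicate 1 or 2 of day 4 it was 746 or 143. With an estimated correlation 0 lists passed camera, 4 had an unadjusted p under 0.05, and fry called 6 where the preset correlation gave 10. On the log2(TPM + 1) scale 35 genes were called higher and 23 lower.

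In irradiated organoids, day 7 against day 4 shows what changed over the same days after 6 Gy. All 20 mitosis and all 20 replication genes rose, with medians of 0.81 (camera adjusted p = 6.21e-10, adjusted p = 0.299 with an estimated correlation) and 0.65 (camera adjusted p = 5.16e-09, adjusted p = 0.299 with an estimated correlation). Mki67 rose from 484 ± 48.1 to 724 ± 9.46 CPM (SD, n = 2). Of the 26 enterocyte markers 24 fell and 1 rose, with a median of -1.70 (camera adjusted p = 2.25e-09, adjusted p = 0.299 with an estimated correlation), Apob from 2511 ± 98.2 to 1031 ± 15.9 CPM. Of the 20 stem cell markers 13 rose and 1 fell, with a median of 0.60 (camera adjusted p = 9.71e-06, adjusted p = 0.299 with an estimated correlation), Lgr5 from 179 ± 19.7 to 292 ± 3.67 CPM and Smoc2 from 235 ± 48.3 to 452 ± 18.9 CPM. Of the 25 p53 targets 16 fell and 1 rose, with a median of -0.90 (camera adjusted p = 3.36e-07, adjusted p = 0.299 with an estimated correlation), Cdkn1a by 1.73 and Mdm2 by 1.45 on the log2 scale. In total 4639 genes were called, 2071 higher and 2568 lower, of which 237 and 1151 changed at least 2-fold.

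Markers of 3 secretory cell types fell as well: 19 of 25 enteroendocrine, with a median of -1.75 (camera adjusted p = 2.25e-09, adjusted p = 0.299 with an estimated correlation), 10 of 17 goblet, with a median of -1.07 (camera adjusted p = 1.94e-05, adjusted p = 0.299 with an estimated correlation), and 9 of 17 Paneth markers, with a median of -1.64 (camera adjusted p = 7.88e-05, adjusted p = 0.353 with an estimated correlation). Examples are Cck, from 67.6 ± 7.67 to 18.5 ± 0.669 CPM, Muc2, from 529 ± 178 to 108 ± 5.55 CPM, and Lyz1, from 941 ± 368 to 299 ± 2.28 CPM. Tuft markers, also secretory, did not pass (median -0.30, camera adjusted p = 0.686), with Avil higher (1.58) and Hpgds (-1.5) and Kctd12 (-1.70) lower of 10. The call of Hpgds was lost without irradiated replicate 1 of day 4 or either irradiated library of day 7 (adjusted p up to 0.0909). Interferon genes fell in 14 of 22 cases, with a median of -2.23 (camera adjusted p = 3.77e-05, adjusted p = 0.436 with an estimated correlation), and NF-kB genes in 8 of 16, with a median of -1.13 (camera adjusted p = 7.88e-05, adjusted p = 0.258 with an estimated correlation). Without irradiated replicate 2 of day 4 the interferon median was -1.05, and DESeq2 called 17 and limma-voom 5 of these genes. The summed immune markers went from 11.6 and 13.8 CPM at day 4 to 5.61 and 7.34 CPM at day 7. Tnfaip3 fell by 1.17 on the log2 scale. YAP targets fell in 7 of 19 cases, with a median of -0.73 (camera adjusted p = 0.00780, adjusted p = 0.299 with an estimated correlation), a call lost without irradiated replicate 1 of day 4 (median -0.22, adjusted p = 0.123). Fetal-like genes fell in 10 of 21 cases, with a median of -0.83 (camera adjusted p = 0.00780, adjusted p = 0.524 with an estimated correlation), with Anxa2 at -1.16. Clu (-0.24, adjusted p = 0.763) and Anxa1 (-0.83) were not called. The list call was lost without irradiated replicate 1 of day 4 (median -0.14, adjusted p = 0.543). Repair genes rose in 14 of 20 cases, with a median of 0.62 (camera adjusted p = 1.01e-06, adjusted p = 0.299 with an estimated correlation), and stress genes in 8 of 16 with 1 lower, with a median of 0.32 (camera adjusted p = 0.00344, adjusted p = 0.299 with an estimated correlation). Mitochondrial transcripts fell in 12 of 13 cases, with a median of -1.22 (camera adjusted p = 2.87e-05, adjusted p = 0.373 with an estimated correlation). DESeq2 called 9 of the repair genes. Without irradiated replicate 2 of day 4 the medians were 0.53 for stress genes and -0.78 for mitochondrial transcripts. After irradiation, adjusted over the list alone, 20 mitosis, 20 replication, 15 repair, 15 stem and 9 stress genes were higher, 25 enterocyte, 19 enteroendocrine, 16 p53, 11 goblet, 9 Paneth, 18 interferon, 10 NF-kB, 10 fetal-like, 8 YAP, 13 mitochondrial, 1 stem and 2 stress genes lower, and 1 enterocyte marker and 1 p53 target higher.

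A further 6 lists did not pass camera after irradiation. Of 10 Wnt targets 5 rose and 0 fell (median 0.34, adjusted p = 0.0827): Axin2 (0.89), Nkd1 (1.40), Sp5 (0.95), Znrf3 (0.49) and Rnf43 (0.40). Of 14 prostaglandin genes 3 rose, such as Pla2g4a (0.80), and 4 fell, such as Slco2a1 (-1.68) and Hpgd (-1.25; median 0.02, mean -0.47, adjusted p = 0.602). Of 7 senescence genes Cdkn1b rose (0.75) and Cdkn2b fell (-0.93; median -0.49 with a test direction upward, adjusted p = 0.981). Of 22 sterol genes 4 rose, such as Acat2 (0.45), and 2 fell, Stard4 (-0.35) and Msmo1 (-0.47; median -0.03 with a test direction upward, adjusted p = 0.686). Of 15 NRF2 targets 5 rose, such as Gpx2 (1.12), and 5 fell, such as Gsta1 (-1.09; median 0.05, adjusted p = 0.686). The calls of Rnf43, Cdkn2b and Stard4 were lost without irradiated replicate 2 of day 7 (adjusted p up to 0.0537, 0.132 and 0.142), and the last 2 also without replicate 1, Cdkn2b without irradiated replicate 2 of day 4 as well, where Stard4 had -0.23. Of 5 mesenchymal markers 0 were called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 (median -0.83, camera adjusted p = 0.478). On the log2(TPM + 1) scale the medians of the tuft, senescence and sterol lists were above 0, at 0.20, 0.30 and 0.35, where that of all genes was 0.30. Adjusted over the list alone, the counts higher and lower were 0 and 2 for tuft, 5 and 0 for Wnt, 3 and 4 for prostaglandin, 1 and 1 for senescence, 4 and 2 for sterol, 6 and 5 for NRF2 and 0 and 0 for mesenchymal genes.

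Among the lists too small for camera, 2 of 4 immune markers fell after irradiation, Lyz2 (40 to 10 counts, -1.97) and Itgam (-1.15), with a list median of -1.20. Of the 4, DESeq2 called 0 and limma-voom 2. Of 3 endothelial markers 2 fell, Pecam1, from 31 to 3 counts (ratio 10.1, counting interval 3.16 to 51.8), and Tek (-2.04), with a list median of -2.04. Of the 3, DESeq2 and limma-voom called 1 each. Of 4 ileal genes 2 fell, Slc51b (-1.91) and Slc51a (-1.83), with a median of -1.81, and Klf4 fell (-0.84) while Myc was not called (-0.17). The calls of Lyz2, Itgam, Pecam1, Tek, Slc51a and Slc51b were each lost without irradiated replicate 1 of day 7 (adjusted p up to 0.226, 0.282, 0.132, 0.226, 0.107 and 0.0627 over all such fits), and that of Klf4 without irradiated replicate 2 of day 7 (0.0693). Those of Lyz2, Itgam, Pecam1, Slc51a and Slc51b were also lost without irradiated replicate 2 of day 4, and all of these but Slc51b, and Tek, without irradiated replicate 2 of day 7. The calls of Lyz2, Itgam and Tek were lost without either control of day 7, that of Lyz2 without irradiated replicate 1 of day 4, and that of Tek without either control of day 4. Without irradiated replicate 1 of day 7 the log2 fold change was -3.06 for Lyz2 and -0.76 for Itgam. Adjusted over the list alone, 2 immune, 2 endothelial and 3 ileal genes and 1 reprogramming factor were lower.

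Among genes with a mean of at least 5 CPM that met the rule's other limits, the largest falls after irradiation were those of Gal3st2, from 421 counts to 1 (ratio 412, counting interval 73.6 to 16329), the noncoding RNA H19, from 10.3 ± 2.59 to 0.315 ± 0.276 CPM, Slc7a15 (-4.46), Slc5a12 (-4.42) and Ifit1 (-5.42). Ifit1 was at 3.66 CPM in irradiated replicate 1 and 39.6 CPM in replicate 2 of day 4, and its call was lost without any 1 of the libraries other than these (adjusted p up to 0.203). The largest rises under the same limits were those of Gvin1 (2.26), Prelp (2.20), Pcdh8 (2.13), Vwa2 (1.90) and Angpt2, from 6.65 ± 1.55 to 23.3 ± 1.44 CPM. Prelp and Pcdh8 rose in controls too. Of the 101 gene results named by the rule and called here, 74 kept their call in every fit without 1 library. Without either irradiated library of day 7 the count of calls was 2171 or 2094. Camera called 15 of 22 lists with the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05, and fry called 16. On the log2(TPM + 1) scale, where the median of all genes shifted by 0.30, 3355 genes were called higher and 760 lower.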

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

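Of the tests below, sequencing depth for the gene length pattern, irradiation by day, leaving out a library and the TPM scale were planned. The others were chosen after the result was seen.

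The effects of irradiation at day 4 and day 7 differed past the edgeR threshold for genes named in the text, with values given as the log2 fold change at day 7 less that at day 4. For genes called above control at day 4 they were: Akp3 (-3.88), Alpi (-2.24), Anxa2 (-0.52), Apcdd1 (-0.96), Apob (-1.54), Ccng1 (-0.95), Cdkn1a (-1.12), Cubn (-4.97), Ddx58 (-1.28), Eda2r (-1.01), Gal3st2 (-8.72), Gsta1 (-1.83), Guca2a (-1.30), Habp2 (-1.41), Hpgd (-1.68), Ifit1bl2 (-5.15), Krt20 (-1.09), Ly6a (-3.49), Ly6d (-4.39), Lyz1 (-2.55), Malat1 (-2.41), Mdm2 (-1.39), Mmp7 (-3.84), Npl (-4.75), Pnliprp2 (-0.99), Ptpn14 (-2.61), Rgs5 (-4.41), Slc14a1 (-1.23), Slc2a2 (-2.08), Slc51b (-3.37), Slc7a15 (-5.08), Sp5 (-1.40), Srxn1 (-0.79), Tnfrsf19 (-1.56), Trp53inp1 (-2.24) and Zfp365 (-5.52). For genes called below control at day 4 they were: Aldh1l2 (2.37), Asns (1.16), Atf5 (1.89), Avil (2.41), Bard1 (1.11), Blm (0.64), Cdkn1b (0.78), Cenpf (0.60), Dmbt1 (2.60), Dtl (0.71), Fam129a (2.19), Fras1 (1.51), Gvin1 (2.25), Lgr5 (0.72), Matn2 (2.29), Mcm6 (0.68), Mki67 (0.78), Mthfd2 (1.31), Nusap1 (1.18), Prex2 (3.04), Psat1 (1.31), Pycr1 (1.79) and Shmt2 (1.27). For genes not called at day 4 they were: Kcnq1ot1 (-1.89), Mrpl23 (-1.36), Nqo1 (1.36) and Pcsk1 (-1.13). Of the 71 gene results named by the rule and called for this difference, 25 kept their call in every fit without 1 library and 46 lost it in 1 or more. The calls lost numbered 10 without control replicate 1 and 30 without control replicate 2 of day 4, 2 and 9 without irradiated replicate 1 and 2 of day 4, 38 and 39 without control replicate 1 and 2 of day 7, and 42 and 41 without irradiated replicate 1 and 2 of day 7.

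For the same difference, 14 lists passed camera with the preset correlation and 0 with an estimated one. The median differences were -0.51 for p53 targets, -1.14 for fetal-like genes, 0.84 for mitosis genes, 0.53 for replication genes, 0.63 for DNA repair genes, -1.65 for Paneth markers, -0.53 for goblet markers, -0.72 for enteroendocrine markers, -1.80 for enterocyte markers, -1.42 for interferon genes, -0.75 for NF-kB genes, 0.24 for sterol synthesis genes, 0.30 for stress response genes and -0.95 for mitochondrial transcripts.

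The first pattern is that interferon-stimulated genes were higher in replicate 2 than in replicate 1 of the irradiated day 4 organoids, in 22 of 22 members, with a median log2 ratio of 1.52 and medians against the controls of 0.69 and 2.37. Immune cells in that library are argued against by the immune markers, whose summed CPM was 1.19 times that of replicate 1, where the interferon genes stood at 3.02 times. Scaling or depth is argued against by 10000 random lists of genes of like level, among which the interferon median lay at percentile 100. A control library under a wrong label is argued against by the p53 targets, whose median in replicate 2 was 0.81 above the control mean. A difference between the cultures may remain, which was not tested, and the labels give no batch.

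The next pattern is that long genes were lower and short genes higher in irradiated organoids at day 7: the rank correlation of expression with gene length, taken as the deviation from the mean of all libraries, was -0.259 and -0.255 in these libraries. Lower depth is argued against by the thinning of all libraries to 7529830 counts, after which the difference from the day 7 controls was -0.336. The length trend as the whole cause of the day 7 calls is argued against by 687 of the 1216 calls, which remained in the same direction with the trend removed. A difference in library or RNA quality cannot be told apart from an effect of irradiation, since both libraries of this group and no other show the trend (lowest correlation among the other 6 libraries 0.0385). Which it may be stays open.

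The last pattern is that enterocyte and Paneth markers were higher and mitosis genes lower in irradiated organoids at day 4. A lower share of dividing cells alone would raise the markers of every other cell type alike, and is argued against by the tuft markers, whose median over the 10 of 21 members with enough counts to test was -1.92, with a range of -1.96 to -1.55 without 1 library, although their camera call was lost without control replicate 2 of day 4 (adjusted p = 0.0566). Replicate 2 of this group alone is argued against by the enterocyte median without it, 2.27, with 2.51 for Paneth and -0.68 for mitosis genes. The scaling of the libraries is argued against by the log2(TPM + 1) scale, on which the medians were 2.44, 2.62 and -0.99, with the tuft median at -0.66, or -0.49 relative to all genes. A change in cell composition, or in the expression of each cell, may underlie it as a hypothesis found and tested on the same data, and bulk RNA does not separate these.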

How the results depend on the processing

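Fits with weights by group or the length trend removed were chosen after seeing the data. Values are for irradiation at day 4, at day 7, by day, and day 7 against day 4 in control and irradiated organoids. EdgeR called 5130, 1216, 1422, 382 and 4639 genes. DESeq2 size factors gave 5146, 1213, 1445, 378 and 4636, DESeq2 3818, 888, 1129, 429 and 3347, limma-voom 5172, 855, 1236, 303 and 4231, and the stricter filter 4692, 1288, 1564, 411 and 4286. No filter gave 5629, 2044, 2456, 1217 and 5124, log2(TPM + 1) 2836, 387, 308, 58 and 4115, log2(TPM + 0.1) 2783, 389, 338, 55 and 4018, and a fold change of at least 2 1659, 352, 569, 156 and 1388, which keeps a part of the calls by construction. Fits of only the groups compared gave 3228 at day 4, 4732 at day 7 and 620 over time in controls, and weights by group 3562, 4120 and 858. Removing the length trend gave 5153, 771, 1291, 376 and 4441. Apart from the fold threshold, other causes were not tested. A replicate block gave 5153, 1245, 1443, 473 and 4643. Deviations of equally numbered replicates correlated by -0.0355 to 0.0581, which leaves pairing open.

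Leaving out 1 library, where the lone sample is assumed to vary like the other groups, gave 3842 to 5101, 105 to 2341, 244 to 2718, 17 to 1234 and 2094 to 5252 genes and 14 to 18, 6 to 11, 13 to 18, 7 to 11 and 13 to 15 lists. Camera with the preset correlation called 17, 7, 14, 10 and 15 lists, with an estimated correlation 0, 0, 0, 0 and 0 (with 3, 2, 2, 4, 3 at an unadjusted p under 0.05), and fry 17, 4, 12, 6 and 16. The Paneth list over time in controls reversed without control replicate 2 of day 4, to a median of -0.15, the lowest of a range up to 0.97. The cause was not tested. Of 4781 repeats of the called gene results under other alternatives 4301 kept the call and 480 lost it, and of 3022 without 1 library 2406 kept it and 616 lost it, with 0 reversed in edgeR and the other tools. Depth limits genes such as Ptgs1, with at most 5 counts in a library.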

Other observations

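The 3 gene lists below were chosen after their genes were seen to move, so their p-values are too small, and no cause was tested. All 77 cytosolic ribosomal protein genes, many of which share reads with pseudogenes, were lower at day 4 after irradiation (median -0.76, camera adjusted p = 1.40e-28, adjusted p = 0.163 with an estimated correlation), and for 68 of them the effect of irradiation was higher at day 7 than at day 4 (median 0.70, camera adjusted p = 5.02e-32, adjusted p = 0.141 with an estimated correlation). At day 7, 4 of the 77 were lower and 0 higher (median -0.08, camera adjusted p = 0.00506, 0.928 with an estimated correlation). Of 23 genes of the amino acid response tested, 20 were lower and 2 higher at day 4 (median -1.09, camera adjusted p = 6.91e-09, adjusted p = 0.163 with an estimated correlation). Examples are Atf5 (-1.78), Pycr1 (-1.80) and Aldh1l2 (-3.15). For 15 of these genes the effect was higher at day 7 (median 1.16, camera adjusted p = 2.21e-10, 0.141 with an estimated correlation). At day 7, 1 of the 23 was higher and 3 were lower (median 0.12, camera adjusted p = 0.809, 0.928 with an estimated correlation). From day 4 to day 7 in controls, 6 of the 23 were lower and 0 higher (median -0.46, camera adjusted p = 1.72e-06, adjusted p = 0.380 with an estimated correlation), and of the hypoxia genes 1 was lower and 0 higher (median -0.63, camera adjusted p = 1.72e-06, adjusted p = 0.431 with an estimated correlation). Of 25 hypoxia genes 11 were lower and 1 higher at day 4 (median -0.95, camera adjusted p = 1.40e-05, adjusted p = 0.337 with an estimated correlation), and 9 were lower and 0 higher at day 7 (median -1.25, camera adjusted p = 1.04e-09, adjusted p = 0.571 with an estimated correlation). Examples are Pgk1 (-1.21 and -1.25), Aldoa (-1.09 and -0.97) and P4ha2 (-1.73 and -2.85). The last 2 lists share Vldlr and Stc2. Asns, Mthfd2, Psat1 and Shmt2 of the amino acid list are in the stress list too.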
